A study of Mus musculus with 2 samples.

How the data were processed

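Gene expression was measured in 2 samples of antigen-presenting cells from 4-week-old female BALB/c mice, 1 from Peyer's patches (lymphoid follicles of the small intestine wall) and 1 from the epidermis. Per the labels, Peyer's patch cells were selected with CD11c beads and then sorted for CD11c, and epidermal cells were selected with MHC class II beads and then sorted for MHC class II as Langerhans cells. The series as a whole used 80 mice, and the cells of each tissue were pooled into 1 sample, so there is 1 array per group and no replicate. Biotin-labelled cRNA was made from 15 ng of total RNA by a two-cycle amplification, per the labels' protocols, and hybridised to an Affymetrix mouse array of 45101 probe sets. A probe set is a group of short probes summarised to 1 value.

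The authors deposited 1 intensity (signal) per probe set and array on a linear scale, and the submitters' processing notes name GCOS, the scanner maker's software. Background method, scaling target, detection calls and genome build are not given in the sources used here. The deposited intensities differed in level between the arrays, and whether the depositors had scaled them is not known. Their trimmed mean, without the lowest and highest 2% of probe sets, was 40.0 in the Peyer's patch sample and 87.1 in the Langerhans cell sample, and their medians were 11.2 and 19.1. The 18 probe sets for hybridisation controls had a median log2 difference, Langerhans minus Peyer's patch, of -0.19 as deposited (range -0.43 to 0.04), and the 24 for poly-A controls had 0.21. The ratio of the 3' to the 5' probe set, a sign of RNA integrity and amplification length, was 2.64 and 3.21 for beta-actin and 2.94 and 3.51 for Gapdh in the Peyer's patch and Langerhans cell samples.

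From these intensities, each array was multiplied to a common trimmed mean (by 1.59 for Peyer's patch and 0.730 for Langerhans cells), which shifted every log2 difference by 1.12 towards Peyer's patch, and the medians of the hybridisation and poly-A controls to -1.31 and -0.91. The controls were thus nearer to equal as deposited, so differences of about this size depend on the choice of scaling. A floor was then set at the higher of the 2 arrays' medians, 17.7 units, and log2 was taken. Of the probe sets, 34958 have 1 gene symbol in the platform's annotation, 932 have several and were left out, and 9211, which include 64 control probe sets, are not listed there with a gene. Symbols were updated through Entrez identifiers with the GRCm38.p6 gene table, which changed 59. No coordinates are given, since no build is stated for the values. For each of 18161 genes the probe set with the highest mean log2 signal was used. A gene counted as measured if it was above the floor on at least 1 array, as 12219 were. With a gene at the floor on 1 array, its fold is a lower bound and is written "at least". Array signal over background limits the precision, and folds between dim genes are the least certain.

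With 1 array per group no test between the groups is possible, and no p-value is given. Genes were counted by size of difference, 4-fold as the main size. The only repeat measurement is that between probe sets of the same gene: their log2 differences had a pooled SD of 0.57, equal to 1.48-fold, over 9753 probe sets of 3736 genes. This SD covers probe choice and transcript isoforms, and not variation between mice, sorts or labelling reactions. For 44 gene lists, of which 14 are markers of other cell types, the median log2 difference was ranked among those of 10000 random lists of the same size matched on mean signal in 20 bins. This percentile describes these 2 arrays and is not a test between conditions, since genes of a list are not independent. It was computed for the 42 lists with at least 5 measured members.

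The design, lists, alternatives and rule for naming genes were fixed before the data were examined. The rule took, per direction, the 10 genes with the largest difference among those above the floor on both arrays and 6 genes at the floor on the dimmer array. The brighter signal had to reach the 75th percentile of its array, and all probe sets above the floor on the brighter array had to point the same way. Clone-type names were passed over. It also took up to 4 members of each list with the largest difference, up to 2 within 2-fold with the highest mean signal, and the genes of the sorting proteins with Cd207. Alternatives were the intensities as deposited, quantile normalization, centring on the median gene, 2 other floors, no floor with 16 added, the median of a gene's probe sets, leaving out probe sets ending in _s_at or _x_at (which can bind several transcripts or genes), sizes of 2-fold and 8-fold, and asking that all probe sets of a gene point the same way. In the median of a gene's probe sets, those at the floor on both arrays were included and count as no difference. Such a median can therefore be small where the probe sets above the floor do not disagree. Analyses used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

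The calculation was tested on simulated data of this comparison, with 200 changed genes, noise of SD 0.4 log2 per array and 11583 measured genes. Of simulated 4-fold genes 46% reached the 4-fold size, and of 8-fold genes 100% did. Of unchanged genes 0.061% reached it, and 3% of 200 unchanged lists of 20 genes fell in the outer 2.5% at either end. The changed genes had a single probe set and a mean signal above 200 units, so changes at the floor and probe choice were not tested. The noise was an assumed value, since variation between mice, sorts and labelling reactions is not known here. The unchanged lists were random genes ranked among random genes, so a low rate was built in.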

Results

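Dendritic cells take up antigen in tissues and present it to T cells, and Langerhans cells are those of the epidermis. The series set the expression profile of Peyer's patch dendritic cells against that of epidermal Langerhans cells, with 1 array of pooled cells for each. After scaling, 10817 genes were above the floor in the Peyer's patch sample and 10339 in the Langerhans cell sample, of 18161 genes with a probe set. Both arrays had 8937 of them in common. Another 1880 were above the floor only in the Peyer's patch sample and 1402 only in the Langerhans cell sample. The floor was the scaled median of the Peyer's patch array, 17.7 units, beside 13.9 for the Langerhans cell array. These counts therefore depend on the scaling and the floor. There are no replicates, so every difference below is between 2 pooled samples and carries no error from biological repeats. The SD between probe sets of the same gene, 0.57 on the log2 scale, is the only spread available. Over genes above the floor on both arrays the log2 signals correlated with Pearson's r = 0.744, a correlation across genes, which are not independent replicates.

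The Langerhans cell sample was marked by langerin and by genes of epidermal keratinocytes, and the Peyer's patch sample by immunoglobulin, B cell and lysozyme genes. Among genes above the floor on both arrays that met the naming rule, those with the largest excess in the Langerhans cell sample were Dsp (desmoplakin, 213-fold), Krt10 (a suprabasal keratin, 192-fold), Anxa8 (179.8-fold), Krtdap (129.8-fold), Lce1c (a cornified envelope gene, 113-fold), Cd207 (langerin, the lectin that defines Langerhans cells, 108-fold), S100a16 (94.9-fold), Emp1 (94.4-fold), Krt79 (78.8-fold) and Mt2 (a metallothionein, 75.6-fold). Krt5, Krt14, Krt15, Krt2, Perp and Calm4 were at the floor in the Peyer's patch sample and at least 288-fold, 223-fold, 238-fold, 258-fold, 251-fold and 234-fold higher in the Langerhans cell sample. In the other direction, by the same rule, the largest excess was that of Ighm (the IgM heavy chain, 293-fold), Lyz2 (122-fold), Bank1 (a B cell scaffold protein, 74.8-fold), H2-Ob (62.3-fold), Lyz1 (58.5-fold), Limd2 (54.8-fold), Mpeg1 (perforin-2, 45.9-fold), Ctse (cathepsin E, 40.3-fold), Gpr18 (40.1-fold) and Ccr6 (31.5-fold). Jchain (the joining chain of IgA and IgM), Igkv8-30, Plac8, Ms4a1 (CD20), Mzb1 and Gimap4 were at the floor in the Langerhans cell sample and at least 559.9-fold, 477-fold, 189-fold, 174-fold, 158-fold and 124-fold higher in the Peyer's patch sample. The immunoglobulin probe sets and Lyz1 and Lyz2 belong to families with near-identical copies, and their signals can be shared. Without probe sets ending in _s_at or _x_at, the log2 difference of Lyz1 was -1.59 in place of -5.87, and that of S100a16 4.64 in place of 6.57. With the median of each gene's probe sets, that of Limd2 was -2.35 in place of -5.78. Probe sets at the floor on both arrays count there as no difference, and the 2 of Limd2 above the floor gave -5.78 and -4.70. With the same setting Emp1 had 4.75 in place of 6.56 and Ctse -4.015 in place of -5.33.

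In all, 988 genes were at least 4-fold higher in the Langerhans cell sample and 527 in the Peyer's patch sample, of 12219 measured, and of these 499 and 277 were at the floor on the dimmer array. At 2-fold the counts were 2151 and 1688. With the signals as deposited, which moves the median gene from -0.04 to 0.997 on the log2 scale, the 4-fold counts became 2058 and 237. For genes above the floor on both arrays, a log2 difference between -1.12 and 0 after scaling was positive as deposited, so such differences have no direction free of the scaling. Most list medians in that range turned positive as well, while those of Fc and complement, cell cycle, mast cell and unrelated-tissue genes stayed negative.

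Genes of unrelated tissues reached 64.5 units in the Peyer's patch sample and 18.2 in the Langerhans cell sample, so a Peyer's patch signal below 64.5 is not clearly above background. The 10 genes with the largest excess in the Langerhans cell sample were all below that, from 17.7 (S100a16) to 35.0 units (Mt2), so their folds are approximate and their order is not settled. With a floor from unrelated genes, 23.5 units, those of Dsp, Anxa8, Emp1, Lce1c and S100a16 are bounds, with log2 differences of at least 7.51, 7.18, 6.44, 6.44 and 6.16. In the other direction those of Bank1, H2-Ob, Ctse and Gpr18 are then bounds too, at -6.11, -5.78, -5.24 and -5.20 or further from 0, as are those of Ccr7, Unc93b1 and Icosl among genes named below, at -3.69, -4.12 and -2.56. The folds of Alox5, Bmpr1a, Cd209c, Epcam, Fosl2, Hpgds, Ier3, Lpl, Ltc4s, Mmp9, Nr4a3, Pdk1, Pvr, Rxra, Tgfbr3, Tjp1 and Tnf, named below, are approximate because their Peyer's patch signals were also below 64.5 units. Counts of genes higher in the Peyer's patch sample also hold some that were below 64.5 units there: 4 of 14 chemokine receptors, 4 of 6 cytokines, 3 of 5 chemokines, 4 of 21 interferon-stimulated genes, 3 of 8 inhibitory genes, 4 of 14 T cell markers and 3 of 17 intestinal markers, with at most 2 in any other list described in this text except the unrelated genes themselves.

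**Figure D1:**
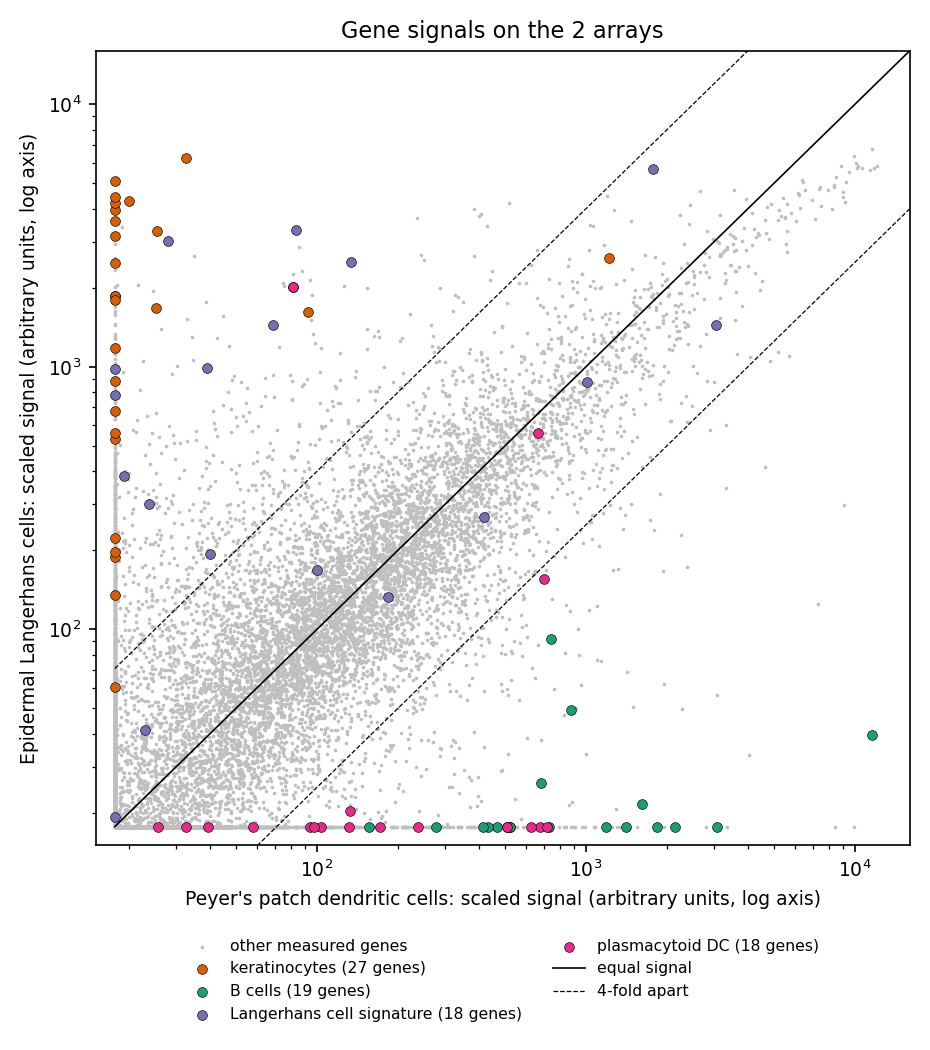
Scaled signal of each measured gene in Peyer's patch dendritic cells (x axis, log scale, arbitrary units) and epidermal Langerhans cells (y axis, log scale, arbitrary units), 1 array each, with signals under the floor of 17.7 drawn at the floor. Coloured points are members of 4 gene lists, the solid line marks equal signal and the dashed lines 4-fold; a gene in several lists has the colour drawn last, and all 27 keratinocyte genes lie on the Langerhans cell side and all 19 B cell genes on the Peyer's patch side.

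Langerhans cell genes were higher in the Langerhans cell sample. Of 18 measured members of that list, 11 were at least 2-fold higher there and 1 (Cd24a, named after its value was seen) in the Peyer's patch sample, and the median log2 difference was 2.96 (percentile 100 among random lists). Besides Cd207, the widest differences were those of Cldn1 (claudin-1, at least 55.3-fold), Gja1 (connexin 43, at least 44.3-fold) and Mfge8 (39.8-fold), whereas Fcgr2b and Tgfbr1 (a receptor for TGF-beta) lay within 2-fold, with log2 differences of -0.21 and -0.64. Keratinocytes, whose markers had a median log2 difference of 6.05 in the same direction, also express 6 of the 18 genes, Cldn1 and Gja1 among them. Without these 6 the median was 1.26 over 12 genes (percentile 99.96), with 6 at least 2-fold higher in the Langerhans cell sample and 0 in the Peyer's patch sample. With the median of its probe sets Cldn1 had a log2 difference of 1.27 in place of 5.79.

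Genes of 2 other dendritic cell types were higher in the Peyer's patch sample. Of 15 measured genes of conventional type 1 dendritic cells, 11 were at least 2-fold higher there and 2 in the Langerhans cell sample, with a median of -2.40 (percentile 0). Wdfy4 (needed for cross-presentation) was 17.5-fold higher, Cd8a at least 14.7-fold and Irf8 (a transcription factor of this lineage) 13.8-fold. By the median of their probe sets, Wdfy4 had a log2 difference of -2.06 in place of -4.13 and Cd8a -2.18 in place of -3.88. T cell markers (median -1.95) and B cell markers (median -4.88) were higher in the same sample. The type 1 list was not recomputed without members that B or T cells share. Whether RNA of these cells accounts for its differences, those of Wdfy4, Cd8a and Irf8 included, was not tested. Plpp1 went the other way, 9.30-fold higher in the Langerhans cell sample, and Id2 and Cadm1 lay within 2-fold. Of 18 genes of plasmacytoid dendritic cells, the interferon-producing type, 14 were at least 2-fold higher in the Peyer's patch sample and 1 (Ly6d, also a keratinocyte marker, named after its value was seen) in the Langerhans cell sample, with a median of -2.50 (percentile 0). They included Klk1 (at least 40.5-fold), Ccr9 (at least 38.0-fold, and -1.62 on the log2 scale by the median of its probe sets), Ptprcap (at least 35.4-fold) and Spib (at least 28.8-fold). B cells share 10 of these 18 genes, and the other 8 had a median of -2.79 (percentile 0). Of 15 genes of conventional type 2 dendritic cells, 6 were higher in the Peyer's patch sample and 4 in the Langerhans cell sample (median -0.46, percentile 6.31). Dtx1 and Cd4 were at least 16.3-fold and 5.10-fold higher in the former, S100a4 and Klf4 15.9-fold and 10.9-fold higher in the latter, and Sirpa and Notch2 were within 2-fold. By the median of all their probe sets, Dtx1 had -2.02 in place of -4.03 on the log2 scale and Cd4 -1.17 in place of -2.35. Each had 1 probe set above the floor.

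Transcription factors of dendritic cells split both ways. Of 27 measured, 11 were at least 2-fold higher in the Peyer's patch sample, led by Spib and Irf8, and 8 in the Langerhans cell sample, led by Nr4a3 (18.5-fold) and Klf4. The median was -0.47 (percentile 1.02), and it became 0.65 with the signals as deposited. With the median of each gene's probe sets the percentile was 13.7. With the same setting Nr4a3 had a log2 difference of 0.00. The 2 probe sets of Nr4a3 above the floor disagreed, with log2 differences of 4.21 and -1.30. Spib is also among the B cell and intestinal epithelial markers, which were higher in the Peyer's patch sample.

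The genes of the sorting proteins were within 2-fold. Itgax, which encodes CD11c, differed by -0.15 on the log2 scale, and the MHC class II genes H2-Aa, H2-Eb1 and H2-Ab1 by -0.76, -0.30 and -0.22. As deposited, all 4 differences were positive, at 0.97, 0.36, 0.82 and 0.90, and H2-Ab1 was at 0.07 by the median of its probe sets. These proteins were used to select the cells, so their levels are no finding between the samples. Of 15 measured genes of class II presentation, 5 were at least 2-fold higher in the Peyer's patch sample and 1 in the Langerhans cell sample (median -0.76, percentile 0.41). H2-Ob and H2-Oa, the chains of the class II regulator H2-O, were 62.3-fold and 11.7-fold higher in the Peyer's patch sample, and Ifi30 (a lysosomal thiol reductase) 3.12-fold, which was under 2-fold as deposited. Without H2-Ob, H2-Oa and Ciita, which B cells also express, the median was -0.36 and the percentile 20.2. The percentile of all 15 was 24.8 after quantile normalization, and their median was 0.36 as deposited. Of 16 genes of class I presentation, 10 were at least 2-fold higher in the Peyer's patch sample and 0 in the Langerhans cell sample (median -1.03, percentile 0.01). The immunoproteasome genes Psmb10, Psmb8 and Psmb9 were 4.90-fold, 3.37-fold and 3.28-fold higher and the class I transactivator Nlrc5 4.32-fold, whereas H2-D1 and Canx were within 2-fold. As deposited, the class I median was 0.088, below that of the median gene, and Psmb8, Psmb9 and Nlrc5 were under 2-fold.

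Maturation genes also split. Of 26 measured, 8 were at least 2-fold higher in the Peyer's patch sample and 5 in the Langerhans cell sample (median -0.50, percentile 1.06; median 0.61 as deposited; percentile 19.7 with the median of each gene's probe sets). Ccr7, the receptor that guides dendritic cells to lymph nodes, had a log2 difference of -4.07, which is a bound of -3.69 with the floor from unrelated genes, since its Langerhans cell signal was 18.1 units. In the Peyer's patch sample Fscn1 (fascin) was 10.3-fold, Traf1 8.62-fold and Icosl 6.08-fold higher. By the median of all its probe sets Fscn1 had a log2 difference of -0.66 in place of -3.36, under 2-fold. Its 2 probe sets above the floor gave -3.36 and -1.33. Cd83 and Birc3 were within 2-fold. B cell markers (median -4.88) and T cell markers (median -1.95) were higher in the same sample as Ccr7, Fscn1, Traf1 and Icosl. The maturation list was not recomputed without genes that B or T cells share, so their RNA as a source was not tested.

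Chemokine receptor genes were mostly higher in the Peyer's patch sample, in 14 of 22 measured, with 3 higher in the Langerhans cell sample (median -1.46, percentile 0). Ccr9, the gut-homing receptor, Ccr6, the receptor for CCL20, and Cxcr4 were at least 38.0-fold, 31.5-fold and at least 18.9-fold higher, and Ccr7 as given above. B cells express 7 of the 22, and without them the median was -1.05 (percentile 0.04). The value of Ccr9 comes from a probe set ending in _x_at, and its log2 difference of -5.25 became -3.50 without such probe sets and -1.62 with the median of its probe sets. S1pr2 was within 2-fold, and so was Gpr183 by its brighter probe set (0.14), whereas the other gave -2.24 and the median of its probe sets -1.05. The 23 measured chemokines showed no common direction, with 7 higher in the Langerhans cell sample, 5 in the Peyer's patch sample and a median of 0.00 (percentile 76.2). Cxcl1 and Cxcl2, which attract neutrophils, were 27.0-fold and 15.6-fold higher in the Langerhans cell sample, and Ccl5 and Cxcl9 at least 29.5-fold and 11.1-fold higher in the Peyer's patch sample. Of 26 cytokine genes, 8 were higher in the Langerhans cell sample and 6 in the Peyer's patch sample (median -0.06, percentile 71.1). Il33 (an alarmin of epithelia) was at least 14.5-fold and Tnf 9.09-fold higher in the former, Ltb (lymphotoxin beta) 26.3-fold and Il16 at least 22.7-fold higher in the latter, and Mif and Ebi3 were within 2-fold. Il16 had -2.10 in place of -4.50 on the log2 scale by the median of its probe sets. Ltb is also among the B cell markers, which were higher in the Peyer's patch sample (median -4.88). Keratinocyte markers (median 6.05) were higher in the same sample as Cxcl1, Cxcl2, Il33 and Tnf.

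**Figure D2:**
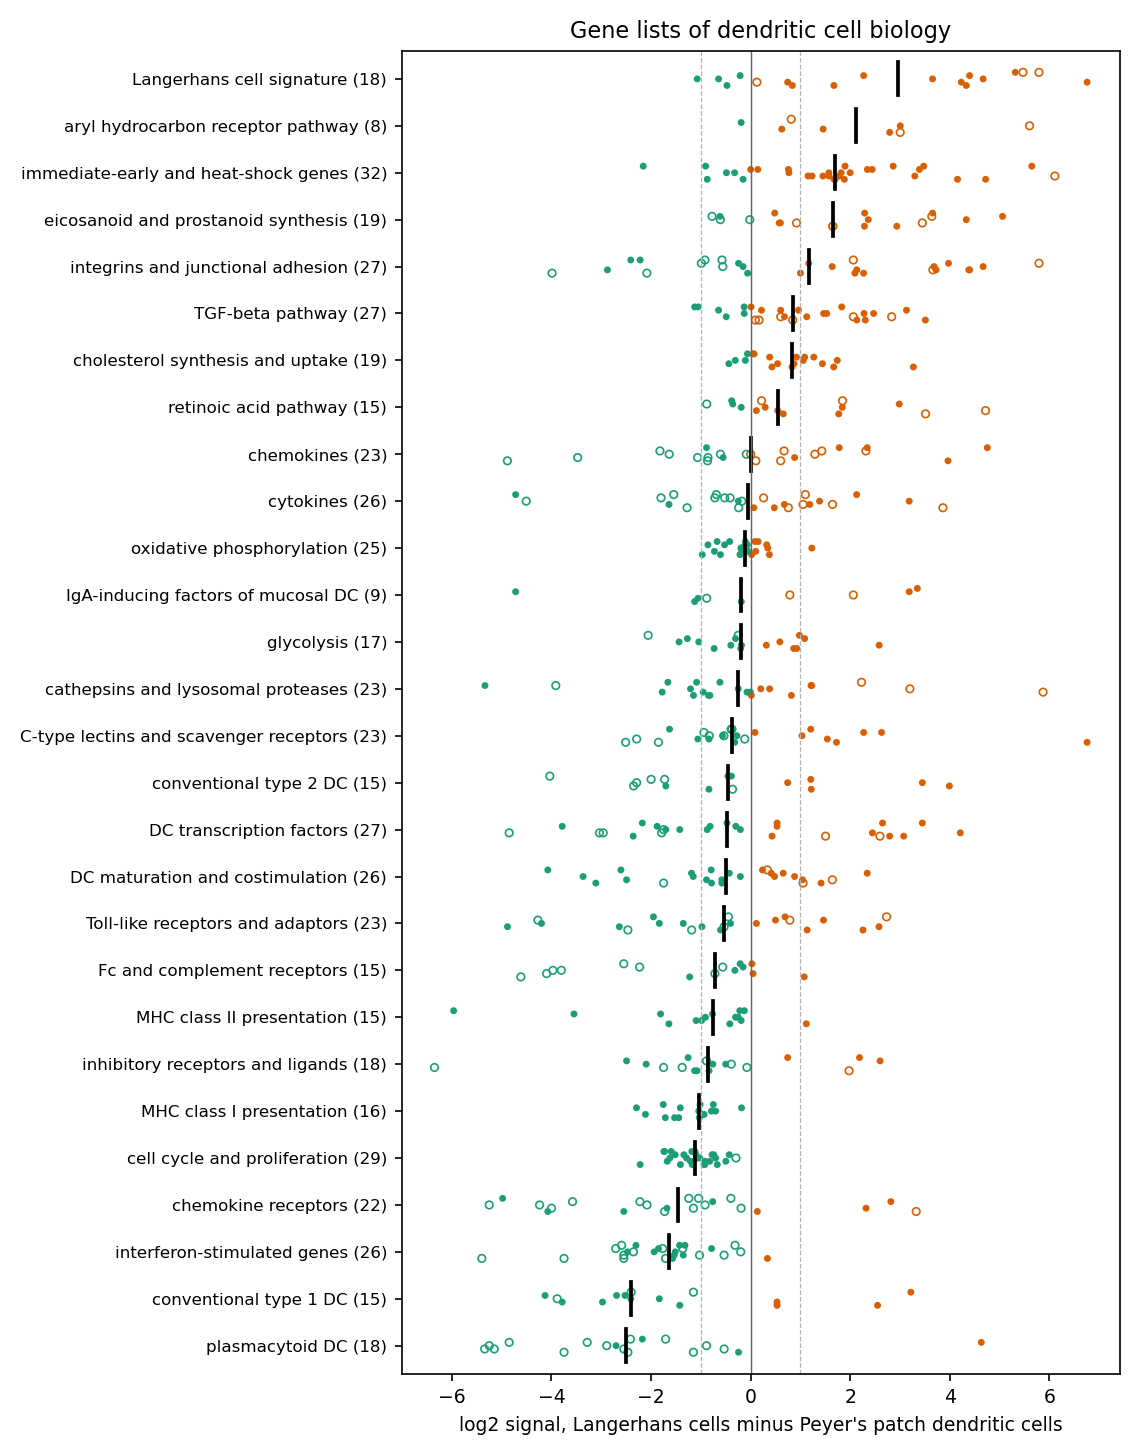
Log2 signal difference, Langerhans cells minus Peyer's patch dendritic cells (x axis), of each measured member of 28 gene lists (y axis, number of measured members in brackets), 1 array per group. Filled points were above the floor on both arrays, open points are bounds, black bars are list medians and dashed lines mark 2-fold; medians run from -2.50 for plasmacytoid dendritic cell genes to 2.96 for the Langerhans cell signature.

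Receptors for microbial products differed by member. Of 23 Toll-like receptor and adaptor genes, 9 were at least 2-fold higher in the Peyer's patch sample and 5 in the Langerhans cell sample (median -0.53, percentile 2.29; median 0.34 as deposited; percentile 2.91 without probe sets ending in _s_at or _x_at). Ly86, Tlr1 and Unc93b1 (a chaperone of endosomal Toll-like receptors) were 29.5-fold, at least 19.3-fold and 18.4-fold higher in the Peyer's patch sample, and Nlrp3 (an inflammasome sensor) at least 6.63-fold higher in the Langerhans cell sample. Myd88 and Irak1 were within 2-fold. B cell markers (median -4.88) were higher in the Peyer's patch sample, as Ly86, Tlr1 and Unc93b1 were. Of 23 lectin and scavenger receptor genes, 7 were higher in the Langerhans cell sample, with Cd209c 6.19-fold, and 5 in the Peyer's patch sample, with Cd36 at least 5.69-fold (log2 difference -0.62, under 2-fold, by the median of its probe sets) and Clec10a at least 4.88-fold (median -0.37, percentile 8.85). Of 15 Fc and complement genes, 7 were higher in the Peyer's patch sample and 1 in the Langerhans cell sample (median -0.72, percentile 0.80; percentile 9.42 with a floor from unrelated genes). Cr2 and Fcer2a, both of B cells, were at least 24.5-fold and 15.7-fold higher and the complement genes C1qb and C1qc at least 17.1-fold and 13.9-fold, whereas Fcgr2b was within 2-fold. Fcer2a had -1.98 in place of -3.97 on the log2 scale by the median of all its probe sets, of which 1 was above the floor.

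Of 18 inhibitory receptors and ligands, 8 were at least 2-fold higher in the Peyer's patch sample and 3 in the Langerhans cell sample (median -0.86, percentile 0.08; median 0.046 as deposited). Btla was at least 81.4-fold and Cd274 (PD-L1) 5.62-fold higher in the former, and Pvr and Havcr2 (TIM-3) 6.06-fold and 4.55-fold higher in the latter. The 6 probe sets of Pvr spanned log2 differences from -0.08 to 3.66. Of 23 cathepsin and lysosomal genes, 7 were higher in the Peyer's patch sample and 5 in the Langerhans cell sample (median -0.25, percentile 27.0). Ctse and Ctsw led in the former, 40.3-fold and at least 15.0-fold, and the cysteine protease inhibitors Cst6 and Csta1 in the latter, at least 58.6-fold and 9.18-fold. Ctss and Cst3 were within 2-fold, Cst3 with a log2 difference of 0.82 that was 1.23 after quantile normalization. Keratinocyte markers (median 6.05) were higher in the same sample as Cst6 and Csta1.

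Several groups were higher in the Langerhans cell sample, as were all 27 keratinocyte markers (median 6.05). Of the lists in this paragraph, only adhesion was recomputed without members that keratinocytes share. For the others, keratinocyte RNA as a source was not tested. Of 27 TGF-beta pathway genes, 12 were at least 2-fold higher there and 2 in the Peyer's patch sample (median 0.85, percentile 100), with Tgfbr3 11.4-fold, Bmpr1a 8.75-fold, Thbs1 at least 7.12-fold and Tgfbi 5.54-fold higher. The 2 probe sets of Tgfbr3 disagreed, at 3.51 and -0.33, with 1.59 by their median, and Skil and Smad4 were within 2-fold. Of 8 measured aryl hydrocarbon receptor pathway genes, 5 were higher there and 0 in the Peyer's patch sample (median 2.12, percentile 99.97). Aldh3a1 was at least 48.5-fold, Tiparp 8.03-fold, Cyp1b1 at least 8.02-fold and Ahr itself 6.93-fold higher, and its partner Arnt was within 2-fold. By the median of their probe sets Cyp1b1 had a log2 difference of 0.40, under 2-fold, and Ahr 1.78 in place of 2.79. Of 19 eicosanoid genes, 11 were higher there and 0 in the Peyer's patch sample (median 1.65, percentile 100). Alox5 (5-lipoxygenase), Hpgds and Ltc4s, which make leukotrienes and prostaglandin D2, were about 33.3-fold, 20.1-fold and 12.6-fold higher, from Peyer's patch signals of 30.2, 19.2 and 23.8 units. Ptger3 was at least 12.4-fold higher (log2 difference 1.82 in place of 3.64 by the median of all its probe sets, of which 1 was above the floor). Of 27 adhesion genes, 15 were higher there and 5 in the Peyer's patch sample (median 1.17, percentile 100), led by Cldn1, Epcam (25.4-fold), Cdh1 (E-cadherin, 21.1-fold) and Tjp1 (20.8-fold). Keratinocytes express 13 of these 27, and without them the median was -0.58 (percentile 3.03). With the median of each gene's probe sets, in which those at the floor on both arrays count as no difference, the median of the 27 was 0.00 (percentile 63.8).

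Retinoic acid genes gave 6 of 15 at least 2-fold higher in the Langerhans cell sample and 0 in the Peyer's patch sample (median 0.54, percentile 94.6). Adh7 and Rarg were at least 26.3-fold and 11.4-fold and Rxra 7.91-fold higher. By the median of their probe sets, Rxra had a log2 difference of 0.82, under 2-fold, in place of 2.98, and that of Rarg was smaller than its 3.51 but still above 2-fold. Keratinocyte markers (median 6.05) were higher in the same sample. Aldh1a2, the retinaldehyde dehydrogenase linked to gut dendritic cells, had a signal of 32.6 units in the Peyer's patch sample and was at the floor in the Langerhans cell sample, and neither this signal nor the difference is clear of background. The log2 difference was -0.88, -2.10 with the lower floor, -0.47 with the floor from unrelated genes and -0.11 as deposited, and Aldh1a1 differed by -0.19 on the log2 scale. Of 9 measured factors linked to IgA induction by mucosal dendritic cells, 3 were higher in the Peyer's patch sample and 3 in the Langerhans cell sample (median -0.19, percentile 38.4). Ltb was the widest in the former, and Mmp9 (10.2-fold), Tnf and Itgb8 (at least 4.18-fold) in the latter. Ltb is also among the B cell markers, which were higher in the Peyer's patch sample (median -4.88).

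Interferon-stimulated genes were higher in the Peyer's patch sample in 21 of 26 measured and in the Langerhans cell sample in 0 (median -1.64, percentile 0). Ifi47 was at least 42.1-fold, Irf7 at least 13.4-fold, Gbp3 at least 6.53-fold and Rtp4 at least 6.02-fold higher, and Oas2 and Usp18 were within 2-fold. The B cell markers (median -4.88) were higher in the same sample as the interferon-stimulated, cell cycle, class I and inhibitory lists. Of 29 cell cycle genes, 18 were at least 2-fold higher there and 0 in the Langerhans cell sample (median -1.12, percentile 0). Cenpe was 4.65-fold, Mcm2 3.34-fold, Rrm2 3.32-fold and Ccnb2 3.19-fold higher, and Pcna and Cdc20 were within 2-fold. As deposited, Mcm2, Rrm2 and Ccnb2 were under 2-fold. As deposited, the cell cycle median was -0.0083, at percentile 0 beside a median gene of 0.997. Immediate-early and heat-shock genes went the other way, with 22 of 32 at least 2-fold higher in the Langerhans cell sample and 1 in the Peyer's patch sample (median 1.69, percentile 100). Hspb1 was at least 69.0-fold, Atf3 26.3-fold and, from Peyer's patch signals of 19.1 and 26.4 units, Ier3 about 50.04-fold and Fosl2 about 17.8-fold higher, while Fos and Hspa8 were within 2-fold. The keratinocyte markers were higher in this same sample (median 6.05).

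Markers of other cell types stood out on both arrays. All 27 measured keratinocyte markers were at least 2-fold higher in the Langerhans cell sample (median 6.05, percentile 100), with Krt5 at 5102 units against 10.8 and Krt14 at 3943 against 8.55 in the Peyer's patch sample. All 19 B cell markers were at least 2-fold, and at least 4-fold, higher in the Peyer's patch sample (median -4.88, percentile 0), with Ighm at 11616 units against 39.6, Ms4a1 at 3082 against 11.05, Cd22 at least 121-fold and Pou2af1 at least 104-fold higher. Of 10 plasma cell markers, 8 were higher there and 1 in the Langerhans cell sample (median -1.83, percentile 0). Among them Jchain read 9917 units against 10.1 and Igha, the IgA heavy chain, was 30.7-fold higher. T cell markers gave 14 of 18 higher there and 2 in the Langerhans cell sample (median -1.95, percentile 0), with Cd2 at least 15.9-fold, Cd28 at least 9.97-fold and Cd3g at least 8.76-fold. Of 10 NK and innate lymphoid markers, 5 were higher there, including Gzma (granzyme A, at least 109.9-fold) and Gzmb (at least 21.6-fold), and 2 in the Langerhans cell sample, where Gata3 was at least 19.8-fold higher (median -1.40, percentile 0.03). Of 19 monocyte and macrophage markers, 10 were higher in the Peyer's patch sample, led by Plac8, Lyz2 and Lyz1, and 4 in the Langerhans cell sample (median -1.22, percentile 0). Without probe sets ending in _s_at or _x_at, the log2 difference of Lyz1 was -1.59 in place of -5.87. Of 23 intestinal epithelial markers, 17 were higher in the Peyer's patch sample, with Fabp2 (an enterocyte fatty acid binding protein) at least 60.6-fold and Fabp1 at least 16.6-fold, and 1, Epcam, in the Langerhans cell sample (median -2.13, percentile 0). As a measure of background, 13 of 56 genes of unrelated tissues were above the floor, 12 in the Peyer's patch sample and 2 in the Langerhans cell sample, and 5 of them were at least 2-fold higher in the former (median -0.34, percentile 3.91). The brightest of these 5, Cela1, read 64.5 units, so dim genes under about that signal are the least certain in the Peyer's patch sample.

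**Figure D3:**
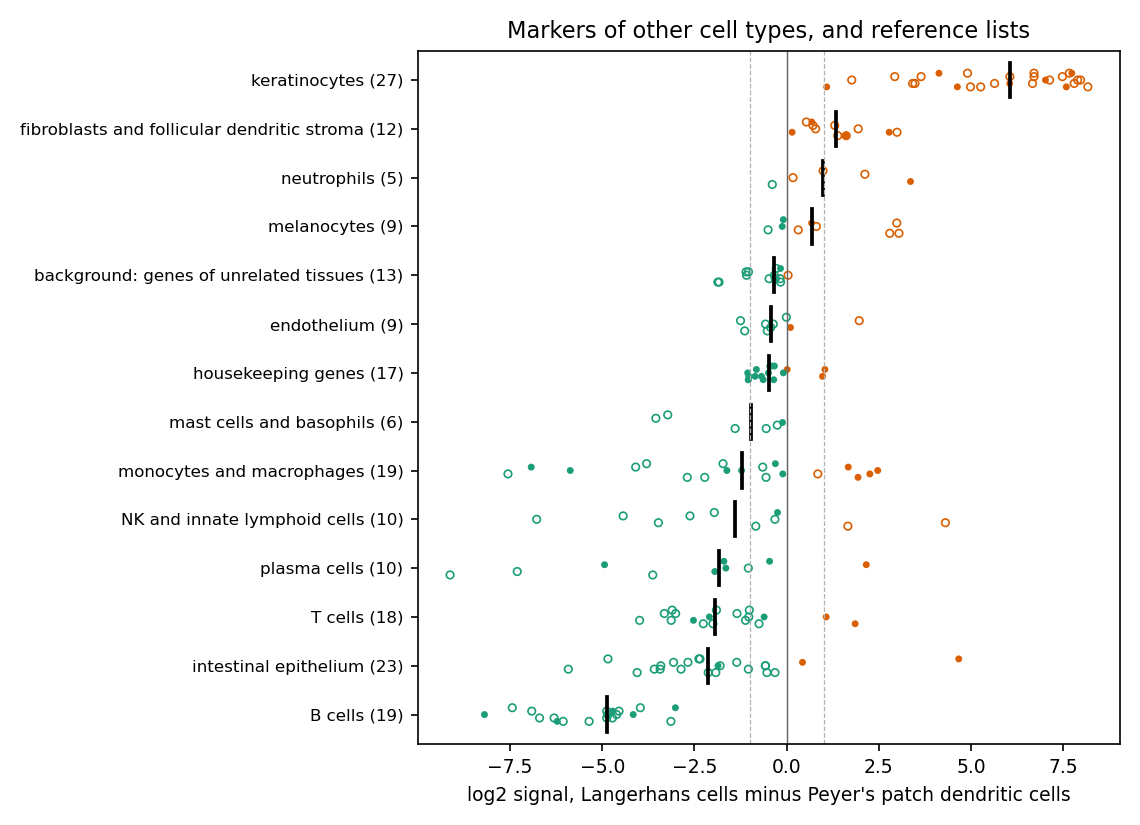
Log2 signal difference, Langerhans cells minus Peyer's patch dendritic cells (x axis), of each measured marker of other cell types and of 2 reference lists (y axis, number of measured members in brackets), 1 array per group. Filled points were above the floor on both arrays, open points are bounds, black bars are medians and dashed lines mark 2-fold; keratinocyte markers (median 6.05) and B cell markers (median -4.88) lie at the 2 ends.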

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

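The tests of explanations in this part were all chosen after the results they bear on had been seen. Of 3584 probe sets above the floor on at least 1 array for which the annotation used here lists no gene, 86 were at least 4-fold brighter in the Langerhans cell sample, with scaled signals up to 2115, and 244 in the Peyer's patch sample, with scaled signals up to 10357. They drew attention because the gene comparison does not use them.

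Keratinocyte markers were brighter in the Langerhans cell sample, in 100% of the 27 measured at 2-fold, with Krt5 at 5102 units and Krt14 at 3943. Multiplying an array moves all genes alike, so array scaling as the cause is argued against by the excess of their median over that of all genes, 5.91 on the log2 scale at the lowest of the 4 scalings. Keratinocyte RNA in the sample is a candidate explanation, since such cells bring all their abundant transcripts, although sorting for MHC class II would remove keratinocytes that lack it. A tissue difference of the Langerhans cells as the only source is argued against, for these markers as a set. All 27 were chosen as markers of keratinocytes, and 25 of them were at least 4-fold higher in the Langerhans cell sample. Their median log2 difference was 6.05, beside an SD between probe sets of 0.57. Whether Langerhans cells add to the signal of single markers was not tested.

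B cell markers were brighter in the Peyer's patch sample, in 100% of the 19 measured at 2-fold, with Ighm at 11616 units and Ms4a1 at 3082. Plasmacytoid dendritic cells as the only source are argued against by the 8 markers they are not known to share, whose median log2 difference was -4.75. B cell RNA in the sample is a candidate explanation, although sorting for CD11c would remove B cells that lack it. A tissue difference of the dendritic cells as the only source is argued against, for these markers as a set. All 19 were chosen as markers of B cells, and all 19 were at least 4-fold higher in the Peyer's patch sample. Their median log2 difference was -4.88, beside an SD between probe sets of 0.57. Whether dendritic cells add to the signal of single markers was not tested.

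Immediate-early and heat-shock genes were brighter in the Langerhans cell sample. Array scaling as the cause is argued against by the same excess, 1.73 at the lowest, beside an SD between probe sets of 0.57. The 3 scalings that multiply an array leave this excess unchanged apart from the floor, so they are not separate tests. The median of these genes itself was 1.69 after scaling, no more than the shift of 1.12 between scalings and this SD together. As deposited that shift raised it to 2.81, so its size depends on the scaling. Quantile normalization gave 1.70 and centring 1.73. A response to the epidermal isolation cannot be told apart from a tissue difference, because there was 1 isolation per tissue. Keratinocyte RNA as their source was not tested.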

How the results depend on the processing

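No paired analysis was possible because each group had 1 pooled sample, and for the same reason no sample could be left out. The alternatives that left out genes shared between cell types, or asked for 4-fold under all 4 scalings, were chosen after seeing the data. Of 42 lists with a percentile, 30 lay in the outer 2.5% at either end, and 22 of these kept their end under every processing alternative that gave a percentile. These alternatives vary the processing and do not test a mixture of cell types in a sample. Centring shifts all genes alike and cannot change a percentile. The other 8 were transcription factors, maturation, MHC class II, Toll-like receptors, Fc and complement, adhesion, neutrophils and melanocytes. Neutrophils had under 5 measured genes, and so no value, with the floor from unrelated genes and without probe sets ending in _s_at or _x_at, as endothelium had as deposited. The SD between probe sets ranged from 0.47 to 0.71. Signal over background limits dim genes. Unless stated, the cause of a change was not tested.

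Genes at least 4-fold higher numbered 2058 in the Langerhans cell and 237 in the Peyer's patch sample as deposited, a setting that also sets its own floor. At 2-fold they numbered 2151 and 1688, and at 8-fold 487 and 237. Under all 4 scalings 977 were at least 4-fold higher in the Langerhans cell sample and 237 in the Peyer's patch sample, the latter no fewer than as deposited alone.

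As deposited, medians that turned from negative to positive were 0.65 for transcription factors, 0.61 for maturation, 0.36 for MHC class II, 0.088 for MHC class I, 0.34 for Toll-like receptors and 0.046 for inhibitory genes. So did those of type 2 dendritic cells at 0.44, lectins at 0.80, cathepsins at 0.87, glycolysis at 0.92, oxidative phosphorylation at 1.01, IgA factors at 0.93, cytokines at 1.29 and housekeeping genes at 0.63. Lists that stayed negative were type 1 dendritic cells at -1.28, plasmacytoid dendritic cells at -1.69, Fc and complement at -0.10, chemokine receptors at -0.76, interferon-stimulated genes at -0.81, cell cycle at -0.0083 and unrelated tissues at -0.029. Among markers, B cells had -4.11, plasma cells -0.70, T cells -1.05, NK and innate lymphoid cells -1.19, mast cells -0.62, intestinal epithelium -1.61 and monocytes and macrophages -0.50. Medians further above 0 were 1.62 for TGF-beta, 1.24 for retinoic acid, 3.41 for eicosanoids, 2.29 for adhesion, 1.95 for cholesterol, 2.81 for immediate-early genes and 6.91 for keratinocytes. Actb, Eef1a1 and Pgk1 turned to 0.082, 0.065 and 0.081.

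Quantile normalization gave 2.32 for the Langerhans cell signature and 1.55 for the aryl hydrocarbon receptor list. A floor at the 30th percentile gave 2.27 and 1.46 for these, -3.50 for plasmacytoid dendritic cells, -2.14 for chemokine receptors, 0.60 for adhesion, 7.02 for keratinocytes, -6.10 for B cells, 0.28 for neutrophils, -3.03 for intestinal epithelium and -1.02 for endothelium. A floor from unrelated genes gave 3.65 for the Langerhans cell signature. The median of a gene's probe sets gave 2.23 for that list, -1.45 for type 1 and -1.90 for plasmacytoid dendritic cells, 1.14 for the aryl hydrocarbon receptor, 0.00 for adhesion and melanocytes, -0.65 for monocytes and macrophages and 0.73 for fibroblasts. Without members shared with keratinocytes, the Langerhans cell signature had 1.26 and adhesion reversed to -0.58. Without probe sets ending in _s_at or _x_at, Rfxank reversed to 0.038.

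Of 248 named genes, 197 moved by more than the SD between probe sets as deposited and 3 with at least a 2-fold difference reversed, against 8 and 0 with quantile normalization. With the lower floor 78 moved, with 16 added 56, with the median of a gene's probe sets 49, and of 244 without probe sets ending in _s_at or _x_at 14 moved and 1 reversed. With centring, which took the median gene from -0.04 to 0, and with the floor from unrelated genes, 23.5 in place of 17.7 units, 0 moved. Changes this small could hardly move a gene by more than the SD, so these settings are little of a test. As deposited, genes above the floor on both arrays all shift by 1.12, so many of the 197 follow from that shift alone. By the median of a gene's probe sets, log2 differences smaller by over 1 and not given above included 4.21 for Gja1, 3.66 for Adh7, 3.21 for Epcam, 2.82 for Fosl2, 1.82 for Bmpr1a, 1.03 for Pdk1, -5.05 for Cd22, -1.91 for Cxcl9 and -1.29 for Rtp4. Values of this setting can reflect probe sets at the floor on both arrays as well as disagreement between probe sets. Rfxank went to 0.00.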

Other observations

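Some cell types and pathways were not described above. Keratinocyte markers (median 6.05) were higher in the same sample as the melanocyte, fibroblast, neutrophil and cholesterol lists. Melanocyte genes of pigment synthesis, Dct, Tyrp1 and Pmel, were at the floor in the Peyer's patch sample and at least 8.26-fold, 7.93-fold and 6.95-fold higher in the Langerhans cell sample, and the list gave 3 of 9 higher there and 0 in the Peyer's patch sample (median 0.68, percentile 97.8; percentile 68.5 with the median of each gene's probe sets). Of 12 fibroblast and stromal markers, 7 were at least 2-fold higher in the Langerhans cell sample and 0 in the Peyer's patch sample (median 1.35, percentile 99.96), with Fap at least 7.97-fold and Clu 6.88-fold. Of 5 measured neutrophil markers, 2 were higher there, Mmp9 and S100a8 (at least 4.35-fold; median 0.99, percentile 98.8; percentile 91.8 with the lower floor). Mucosal mast cell proteases Mcpt1 and Mcpt2 were at least 11.7-fold and 9.36-fold higher in the Peyer's patch sample, in a list with 3 of 6 higher there and 0 in the Langerhans cell sample (median -0.98, percentile 1.13). Of 9 endothelial markers, 2 were higher in the Peyer's patch sample and 1 in the Langerhans cell sample (median -0.43, percentile 9.57). Of 4 measured gamma-delta T cell markers, 2 were at least 2-fold higher in the Peyer's patch sample and 0 in the Langerhans cell sample, but both were below the brightest unrelated gene there (64.5 units), as were both endothelial markers. Of 3 erythroid markers 1, Car2, was higher in the Peyer's patch sample (at least 9.66-fold).

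Among metabolic genes, 7 of 19 for cholesterol synthesis and uptake were at least 2-fold higher in the Langerhans cell sample and 0 in the Peyer's patch sample (median 0.83, percentile 99.8). Lpl (lipoprotein lipase) was 9.63-fold, Hmgcs1 3.34-fold, Fdft1 3.18-fold and Sqle 2.72-fold higher, and Apoe was within 2-fold. By the median of all their probe sets, Lpl had 1.63 on the log2 scale in place of 3.27 and Fdft1 0.80, under 2-fold. Lpl had 1 probe set above the floor, and the 2 of Fdft1 above it gave 1.61 and 1.67. Of 17 glycolysis genes, 4 were higher in the Peyer's patch sample and 2 in the Langerhans cell sample (median -0.20, percentile 31.8), with Hk3 at least 4.16-fold in the former (log2 difference -0.71 without probe sets ending in _s_at or _x_at) and Pdk1 5.98-fold in the latter. By the median of its probe sets Pdk1 had a log2 difference of 1.03 in place of 2.58. Of 25 oxidative phosphorylation genes, 24 were within 2-fold and 1, Uqcrc1, was 2.34-fold higher in the Langerhans cell sample (median -0.11, percentile 59.2). Of 17 housekeeping genes, 12 were within 2-fold, 4 higher in the Peyer's patch sample and 1, Tfrc, 2.05-fold higher in the Langerhans cell sample (median -0.49, percentile 3.66). Tfrc had 0.61 on the log2 scale by the median of its probe sets. As deposited, the medians of these last lists were 1.01 and 0.63, and Actb, Eef1a1 and Pgk1, at -1.04, -1.06 and -1.04 after scaling, were at 0.082, 0.065 and 0.081. The brightest 100 probe sets held 16.4% of all signal in the Peyer's patch sample and 10.5% in the Langerhans cell sample.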
